A study of Rattus norvegicus with 6 samples.

How the data were processed

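The samples were 3 BCP and 3 sBCP ganglion samples as the labels group them, with replicate numbers taken from the titles. The labels do not state that each sample came from a separate animal, so the limma p-values per gene measure the spread between these samples, which may be technical in part. Per the labels' protocols, total RNA (5 µg, RIN above 7) went through repeated purification on poly-T beads and was sequenced in pairs with an insert of 300 bp on an Illumina instrument. The aligner, the counting tool, the annotation release and the genome build were not given in the sources used here, nor was whether counting used strand.

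Per the file headers, the authors deposited FPKM values per Ensembl rat gene and sample. Per the file headers, the table also holds the authors' fold change, which on the values equals the ratio of the mean BCP to the mean sBCP FPKM in all 20046 features with both means above 0, and its log2 as deposited by the authors. The authors deposited a p-value and a q-value per gene from a test not given in the sources used here. The smallest q-value was 14741 times its p-value, which is the number of features with more than 1 FPKM in at least 1 library. Of the authors' p-values 0.861% were under 0.05, where 5% are due by chance, and their median was 0.901. Of these p-values 9126 were exactly 1, and of the other 14674 the share under 0.05 was 1.40% and the median 0.720.

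Depth can be read only in part. Comparing single-transcript features under 0.5 FPKM in every library gave a most frequent ratio between libraries (bins of 0.01 on the log2 scale), which set the relative depth against BCP replicate 1 at 1.31 and 1.23 for BCP replicates 2 and 3 and at 1.15, 1.11 and 1.12 for sBCP replicates 1, 3 and 4. Whole reads were not recovered, so no count test was run and no interval from counts is given. Exact zeros can be failed estimates, since 19 features above 20 FPKM in a library were at 0 in another. Genes listed at 0 are given by library.

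Features with at least 1 FPKM in at least 3 of the 6 libraries (13710 of 23800) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, a trend of variance on mean and no covariate, and Benjamini-Hochberg adjustment at 0.05. A difference on this scale understates the change of low genes. Of 38 gene lists fixed from the tissue and the model, 37 had at least 5 tested genes and were tested with camera (preset correlation 0.01, adjusted over the lists), and again with an estimated correlation and with fry. With an estimated correlation 0 lists were called, and with fry 1, skeletal muscle. The preset correlation treats the members of a list as nearly independent. Its p-values therefore rest on the number of genes and can be far too small where members vary together. The estimated correlation was 0.851 for interferon response and 0.563 for skeletal muscle. Hypergeometric p-values likewise compare genes and do not measure the spread between samples. Terms of the table's own annotation with 10 to 500 tested genes were tested by the hypergeometric distribution against the tested genes with a term. The tests, the lists, a panel of 25 genes and the alternatives were chosen before the data were examined, except where the text says otherwise.

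The genes named are the tested panel genes, the 8 largest rises and falls among the genes that passed with a mean of at least 2 FPKM, non-overlapping groups and a gene symbol, filled up by unadjusted p where fewer passed, and up to 4 members with the smallest unadjusted p of each list described. A gene that this rule takes is not reported here. Gene names and coordinates are those of the deposited table. No library shared its values with another. On simulated values for this comparison (13710 genes, 200 changed), limma recovered 57% of 2-fold and 87% of 4-fold changes, with 9 false calls among 153. The simulated noise was independent between genes, with spreads shuffled over genes and no library standing apart. These rates therefore need not hold for the real values, where genes vary together. Alternatives were other pseudocounts, filters, scalings and variance models, array weights, the replicate number as a block, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9.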

Results

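The data compared lumbar dorsal root ganglia, which hold the cell bodies of sensory neurons, between rats injected in the tibia with living and with boiled tumour cells. Sprague Dawley rats received an injection of 10 µL of medium with MRMT-1 cells, a rat breast carcinoma line, into the left tibia. Living cells were given in the bone cancer pain group (BCP) and boiled cells in the sham group (sBCP). The ganglia of levels L3 to L5 on the injected side were taken on day 17, and polyadenylated RNA was sequenced from 3 BCP samples (replicates 1, 2 and 3) and 3 sBCP samples (replicates 1, 3 and 4). The values were FPKM (fragments scaled to transcript length and library size) for 23800 features, of which 13710 reached 1 FPKM in at least 3 of the 6 libraries and were tested. The summed FPKM lay between 479167 and 495494 per library. The absolute depth was unknown, and low values placed the relative depth of the other 5 libraries at 1.11 to 1.31 times that of BCP replicate 1.

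The comparison of BCP with sBCP asked which transcripts of the ganglia on the injected side differ after living tumour cells. Genes of skeletal muscle were far lower in the BCP samples. Muscle tissue taken along with the sBCP ganglia cannot be told apart here from a change inside ganglion cells. Acta1, the alpha-actin of skeletal muscle, was at 8.57 ± 2.17 FPKM in BCP and 198 ± 47.0 in sBCP (SD, n = 3 each), 23.1-fold lower by the ratio of means. Ckm, the muscle creatine kinase, was at 2.13 ± 0.983 against 101 ± 23.3 FPKM, and the fast myosin light chain Mylpf at 2.38 ± 0.394 against 136 ± 75.0 FPKM. The troponin subunits of fast fibres fell as well, with BCP minus sBCP differences on the log2(FPKM + 1) scale of -5.37 for Tnnc2, -4.61 for Tnnt3 and -4.02 for Tnni2 (standard errors of 0.317, 0.225 and 0.177). The limma adjusted p was 0.000478 for Acta1, 0.000497 for Ckm and 0.00118 for Mylpf, and all 3 BCP libraries lay below all 3 sBCP libraries for each of these genes.

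**Figure D1:**
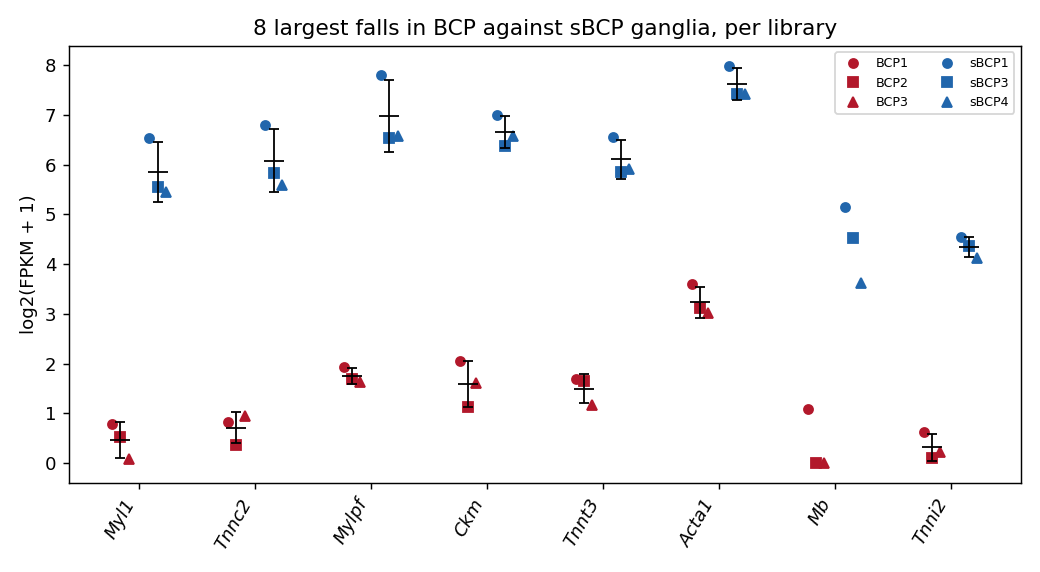
The 8 largest falls in BCP, as log2(FPKM + 1) on the vertical axis for each gene on the horizontal axis, with each library as a point (BCP red, sBCP blue) and the mean ± SD of each group in black. Mb is listed at 0 in BCP replicates 2 and 3 and has no mean or SD drawn; for each of the 8 genes, the 3 BCP libraries lie below the 3 sBCP libraries.

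In all, limma called 2 genes higher and 23 lower in BCP at an adjusted p under 0.05, with 271 genes at an unadjusted p under 0.05 where 685.5 are due by chance. In a check chosen after seeing the data, splitting BCP replicates 1 and 2 with sBCP replicate 4 from the rest gave 2500 such genes. By this count the samples differed more along that split than between the groups. A gene that did not pass is therefore not shown to be unchanged. Of the 23 lower genes, 15 were in the skeletal muscle list or carried a muscle term in the table's gene ontology column. The others were not sorted by tissue, so this count does not show that they are not muscle genes. Of the 15 tested members of the skeletal muscle list, 12 were lower, both over all genes and adjusted over the list alone. The list had a median difference of -4.02 on the log2 scale (camera with a preset correlation, adjusted p = 2.58e-60), and with an estimated correlation the adjusted p = 0.145. Muscle contraction was the leading ontology term among the lower genes, with 6 of its 36 tested genes (hypergeometric adjusted p = 3.92e-08). Other falls included Myl1, a fast myosin light chain, with a difference of -5.38 and a standard error of 0.317 (adjusted p = 0.000955, limma), and Mb, the oxygen-binding myoglobin, which was at 34.2, 22.0 and 11.2 FPKM in the sBCP libraries, at 1.13 in BCP replicate 1 and listed at 0 in BCP replicates 2 and 3. Mb passed in the full set (limma adjusted p = 0.0211), but not without BCP replicate 2 (0.0911), BCP replicate 3 (0.117), sBCP replicate 1 (0.0639) or sBCP replicate 3 (0.132), nor with pseudocounts of 0.1 (0.133) and 0.01 (0.667) or with no filter (0.0751). The count of lower genes was 13 without BCP replicate 3 and 14 without sBCP replicate 3.

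The genes called higher were 2. Wdr77, which encodes a partner of the arginine methyltransferase Prmt5, was at 6.56, 8.03 and 2.95 FPKM in BCP, at 0.0182 and 0.00916 in sBCP replicates 1 and 4, and listed at 0 in sBCP replicate 3 (limma adjusted p = 0.0229). Its interval, chromosome 2 from 208420206 to 208586356 in a build not given in the sources used here, overlaps 6 other features, 3 of them on its strand, so its value is uncertain wherever reads were shared. On that strand LOC100911453 covers almost the same interval, from 208420309 to 208587260, and was at 8.86 to 9.88 FPKM over the 6 libraries. Whether reads were assigned differently between Wdr77 and that feature was not tested. The other, named after its values were seen, was LOC103692785, described in the table as a 60S ribosomal protein L39 gene on chromosome 18, with 22.2 ± 1.01 FPKM in BCP and 9.30 ± 1.36 in sBCP (SD, n = 3 each, adjusted p = 0.0106). It can share reads with near-identical ribosomal protein copies, and its adjusted p was 0.0726, 0.0526 and 0.0571 without BCP replicates 1, 2 and 3 and 0.0511 without sBCP replicate 3. Wdr77 lost its call without BCP replicate 1 (adjusted p = 0.161), BCP replicate 2 (0.0657), sBCP replicate 1 (0.112), sBCP replicate 3 (0.133) and sBCP replicate 4 (0.0908), and with no filter (0.0751). In alternatives chosen after seeing the data, its adjusted p was 0.0818 with the unnamed mitochondrial features as a covariate and 0.0601 without muscle genes. Without BCP replicate 1 no gene was called higher (0 genes, 254 genes of either direction at an unadjusted p under 0.05), and 7 were without sBCP replicate 4. The next genes by unadjusted p among those with non-overlapping groups did not pass. They included Npw, a neuropeptide precursor (2.95 ± 0.108 against 1.59 ± 0.265 FPKM, adjusted p = 0.612), Fxyd3, a regulator of the sodium pump (9.03 ± 1.39 against 5.39 ± 0.629, adjusted p = 0.612), Lrrn3, Smim18, Nqo1 and Tmco3, the last of which was listed at 0 in sBCP replicates 1 and 4 and was called without sBCP replicate 3 (adjusted p = 0.00571). Non-overlapping groups were seen in 740 tested genes, 5.4%, where chance gives 10%.

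Genes of pain-sensing neurons did not pass the test singly. Of a panel of 25 genes, 20 were tested and limma called none (adjusted p of 1.00 for each). Calca, the precursor of the neuropeptide CGRP, was at 513 ± 22.3 FPKM in BCP and 504 ± 55.2 in sBCP, and Tac1, the substance P precursor, at 133 ± 12.5 against 147 ± 5.76 FPKM (SD, n = 3 each). The heat-gated channel Trpv1 was at 37.1 ± 3.86 against 39.7 ± 2.17 FPKM, with a 95% interval of the log2 difference from -0.32 to 0.12. The sodium channel Scn10a was at 97.8 ± 6.92 against 108 ± 16.6 FPKM, and the ATP-gated channel P2rx3 at 126 ± 5.24 against 139 ± 7.01 FPKM. Intervals were wide for Scn9a (from -0.59 to 0.90) and Trpa1 (from -0.64 to 0.14). The list of nociceptive channels had 12 of its 34 tested members above 0 and 22 below (camera adjusted p = 0.320), and the lists of sensory neuropeptides, neurotrophic factors, potassium channels and pan-neuronal genes were likewise not called. Without sBCP replicate 4, sensory neuropeptides (mean of 0.13, adjusted p = 0.0411) and pan-neuronal genes (0.07, adjusted p = 0.0157) were called higher, and without BCP replicate 3 potassium channels were called lower (-0.09, adjusted p = 0.0344). The nonpeptidergic and itch neuron list, which holds P2rx3 and Mrgprd, had 2 of its 15 tested members above 0 and 13 below (mean of -0.14, camera adjusted p = 0.0131), and 0 passed singly over all genes or adjusted over the list alone. For this list the adjusted p = 0.849 with an estimated correlation, and it was 0.0915 and 0.236 without BCP replicates 1 and 2 and 0.362 without sBCP replicate 4. Il6, Il1b, Tnf, Sprr1a and Oprm1 were below the filter. Of these, Sprr1a was at 7.80 FPKM in BCP replicate 2 and at 0.0908 to 0.494 in the other libraries. Il1b was at 1.32 FPKM in BCP replicate 2 and at most 0.615 in the others. Il6, Tnf and Oprm1 stayed under 1 FPKM in every library.

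**Figure D2:**
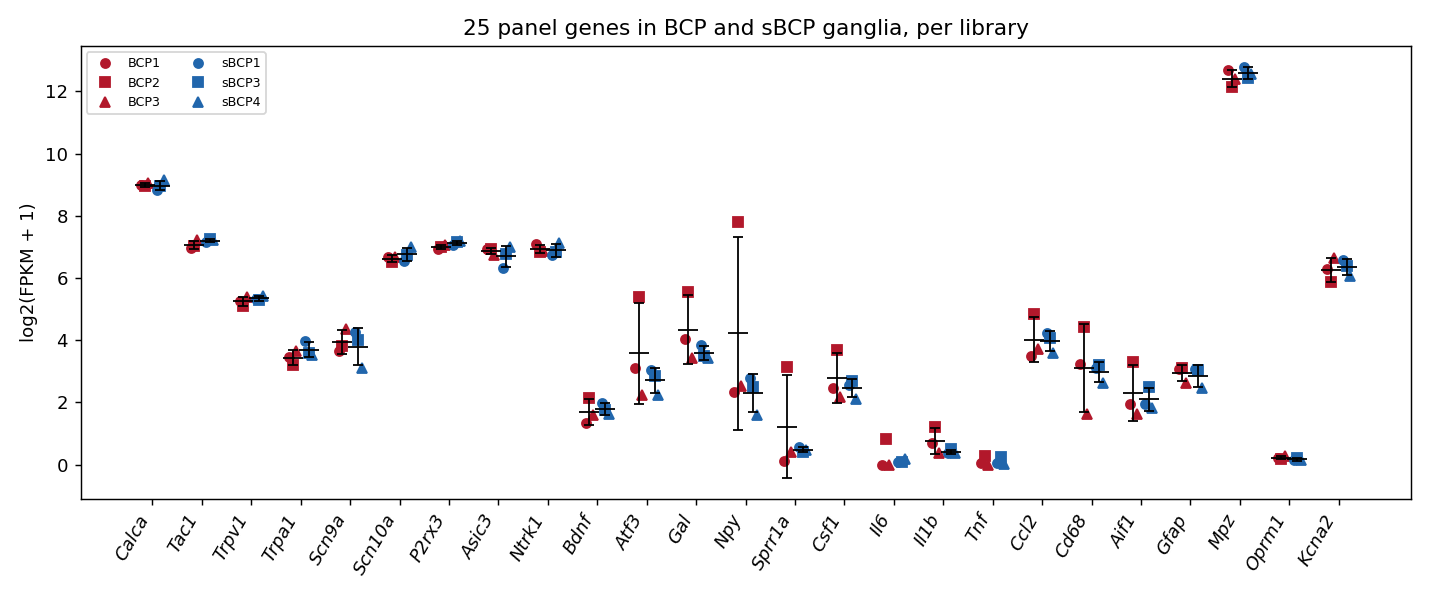
The 25 panel genes as log2(FPKM + 1), with each library as a point (BCP red, sBCP blue) and the mean ± SD of each group in black, left out for genes listed at 0 in a library. Npy was at 224 FPKM in BCP replicate 2 and between 2.05 and 5.92 FPKM in the other 5 libraries.

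Markers of nerve injury and of interferon response were higher in BCP by the list test, through BCP replicate 2. Npy, a neuropeptide induced in injured sensory neurons, was at 224 FPKM in that library, and at 4.06 and 4.71 in the other BCP libraries. Atf3, an injury-induced transcription factor, was at 40.8 FPKM against 7.57 and 3.72, and the neuropeptide Gal at 46.3 against 15.4 and 9.84. The axon injury list had 18 of 21 tested members above 0 and 3 below (mean log2 difference of 0.30, camera adjusted p = 0.00594), and 0 passed singly over all genes or adjusted over the list alone. With an estimated correlation the adjusted p = 0.849 for axon injury. The interferon list had all 32 tested members above 0 (mean difference of 0.46, adjusted p = 2.58e-10, and adjusted p = 0.849 with an estimated correlation), 0 of which passed singly. Its leading gene, Ifit1, was at 8.52, 20.8 and 2.29 FPKM in BCP and at 2.17, 3.59 and 1.03 in sBCP (unadjusted p = 0.0539 by limma). The list scores of MHC class II (1.14), macrophage (0.91), cytokine (0.75) and complement genes (0.74) were also highest in that library, and these 4 lists were not called (adjusted p of 0.474, 0.301, 0.0551 and 0.301). Without BCP replicate 2 the mean difference was -0.12 for axon injury (camera adjusted p = 0.128) and 0.04 for interferon (adjusted p = 0.337), and no list was called higher (0 lists).

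The lists called lower beside skeletal muscle were 9 and moved by small amounts, and each lost its call with an estimated correlation (adjusted p = 0.849 for each). In a check chosen after seeing the data, 8 of the 10 splits of the libraries, the real one included, called at least 12 lists. The list score of skeletal muscle was at -1.47, -1.79 and -1.82 in the BCP libraries and at 2.12, 1.49 and 1.46 in the sBCP libraries. In the fibroblast and extracellular matrix list, 26 of 27 members were below 0 (mean of -0.26, camera adjusted p = 8.10e-05), with Dpt at 1.74 ± 0.742 against 3.89 ± 1.52 FPKM and Pi16 at 4.64 ± 2.19 against 8.37 ± 1.98 FPKM, neither passing singly. In the pericyte and smooth muscle list, 14 of 18 were below 0 (mean of -0.30, adjusted p = 0.000143), led by Des, the intermediate filament desmin that skeletal muscle also holds, at 2.55 ± 0.405 against 11.4 ± 4.15 FPKM (adjusted p = 0.0568). Des was called without sBCP replicate 1 (adjusted p = 0.0324), with a pseudocount of 0.1 (0.0496), median-ratio rescaling (0.0310), quantile normalization (0.0375), array weights that had not converged (0.0107) and the mitochondrial covariate (0.0393). Of this list, 1 member was lower when adjusted over the list alone. It and the immediate early list were not called once muscle genes were left out, an alternative chosen after seeing the data. The myelin list had 20 of 22 below 0 (mean of -0.19, adjusted p = 0.000274), including Egr2, the transcription factor of myelination, at 7.86 ± 1.47 against 11.4 ± 4.04 FPKM. The glucocorticoid list (mean of -0.15, adjusted p = 0.00836) and the immediate early list (mean of -0.15, adjusted p = 0.0189) followed. Erythroid (mean of -0.46, adjusted p = 0.0105), neutrophil (-0.43, 0.0272), nonpeptidergic and itch neuron (-0.14, 0.0131) and mitochondrially encoded genes (-0.13, 0.0416) made up the rest.

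Each of these 9 calls was lost when single libraries were left out. Without sBCP replicate 1, which had the highest score in each of the 9 lists, the adjusted p was 0.113 for fibroblasts, 0.421 for myelin, 0.695 for glucocorticoid response, 0.564 for immediate early genes, 0.248 for erythroid genes, 0.602 for neutrophils and 0.697 for mitochondrially encoded genes. Without BCP replicate 3 it was 0.410 for fibroblasts, 0.113 for pericytes, 0.810 for immediate early genes, 0.158 for erythroid genes, 0.410 for neutrophils and 0.113 for mitochondrially encoded genes. Without BCP replicate 2 it was 0.337 for myelin, 0.181 for glucocorticoid response and neutrophils, 0.443 for erythroid genes and 0.236 for nonpeptidergic and itch neurons. Without sBCP replicate 4 it was 0.230 for erythroid genes, 0.528 for neutrophils and 0.362 for nonpeptidergic and itch neurons, without BCP replicate 1 it was 0.0915 for nonpeptidergic and itch neurons and 0.811 for mitochondrially encoded genes, and without sBCP replicate 3 it was 0.125 for the last. The skeletal muscle list was called in each of the 6 such fits. A lost call did not always go with a smaller mean difference. Without sBCP replicate 4 the mean was -0.443 for erythroid and -0.139 for nonpeptidergic and itch neuron genes (-0.457 and -0.141 in the full set). Without BCP replicate 3 it was -0.159 for mitochondrially encoded genes (-0.134 in full). Other means came near 0, such as -0.00277 for immediate early and 0.00264 for glucocorticoid genes without sBCP replicate 1.

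**Figure D3:**
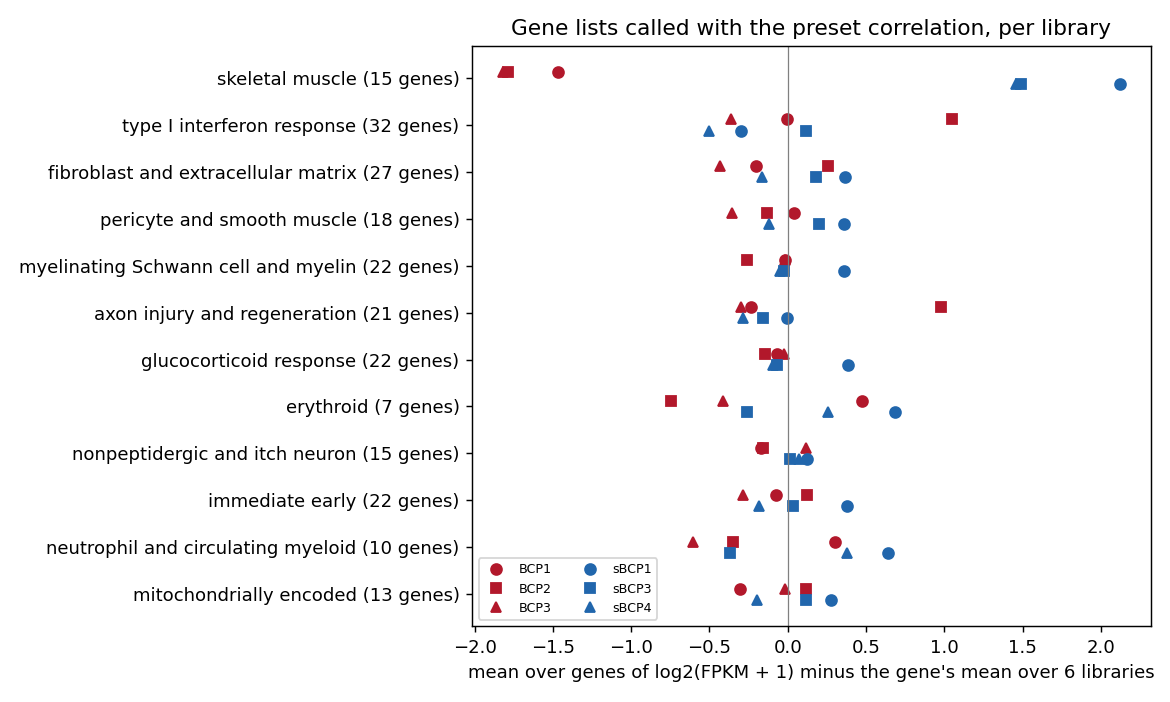
The 12 gene lists called with the preset correlation, with the list score on the horizontal axis (the mean over genes of log2(FPKM + 1) minus the gene's mean over the 6 libraries) and each library as a point (BCP red, sBCP blue). The groups separate for skeletal muscle, from -1.47 at most in BCP to 1.46 at least in sBCP, while BCP replicate 2 alone lies high for interferon response (1.05) and axon injury (0.98).

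The other 25 lists tested were not called, with adjusted p from 0.0551 for cytokines and chemokines to 0.973 for GABA and glutamate receptors. Satellite glia, the cells that wrap the neurons, had 9 of 20 members above 0 (adjusted p = 0.794), and repair Schwann cells 8 of 12 (0.714). Macrophages had 18 of 24 above 0 (adjusted p = 0.301), with Cd68 at 8.53, 20.6 and 2.10 FPKM in BCP and 7.70, 8.15 and 5.12 in sBCP. Without BCP replicate 2 the macrophage list was called lower instead (mean difference of -0.32, adjusted p = 7.45e-06), and without BCP replicate 3 it was called higher (mean of 0.44, adjusted p = 7.13e-06), as it was without sBCP replicate 3 (0.25, adjusted p = 0.0356). MHC class II and complement genes were likewise called lower without BCP replicate 2 (-0.45 and -0.23, adjusted p of 0.000371 and 0.0225) and higher without BCP replicate 3 (0.49 and 0.37, adjusted p of 0.00228 and 0.000534), the latter list also without sBCP replicate 3 (0.24, adjusted p = 0.0370). Cytokines were called higher without BCP replicate 1 (0.32, adjusted p = 0.0114), BCP replicate 3 (0.37, adjusted p = 0.000534) or sBCP replicate 3 (0.29, adjusted p = 0.0124). Markers of epithelial and mammary tumour cells had 5 of 7 above 0 (adjusted p = 0.320), and were called higher without BCP replicate 3 (0.17, adjusted p = 0.0255) or sBCP replicate 4 (0.14, adjusted p = 0.0498). Without BCP replicate 1 ribosomal protein genes were called higher (0.13, adjusted p = 6.74e-06), and without BCP replicate 2 meninges and perineurium were called lower (-0.41, adjusted p = 1.80e-06). Without BCP replicate 3 the endothelial (adjusted p = 0.0103), heat shock (0.00968), oxidative phosphorylation (0.0352) and ribosomal protein lists (0.0303) were called higher. The same held of the endothelial list without sBCP replicate 1 (adjusted p = 0.0273), and of heat shock (0.0411) and oxidative phosphorylation (0.00329) without sBCP replicate 4, while the circadian clock list was called lower without sBCP replicate 3 (0.0356). All list fits without a replicate used camera with the preset correlation, so their p-values can be far too small where members vary together. In the full set the estimated correlation was 0.784 for macrophage and 0.873 for MHC class II genes. The fits without a replicate were not run with it. Adipocyte genes had 2 of 7 above 0 and 5 below (camera adjusted p = 0.450). Of them 1, Fabp4, at 0.710 ± 0.335 FPKM in BCP and 3.68 ± 2.34 in sBCP, was lower when adjusted over the list alone. The lymphocyte list had 4 tested genes and was not tested as a list.

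The authors' deposited table marks 152 genes as significant, 49 higher and 103 lower in BCP, all with an absolute log2 fold change of at least 1.00 and a p-value of at most 0.0487. Of these, 86 were among the genes tested here, and they included all 25 genes that limma called. A q-value under 0.05 in the authors' deposited table was given to 74 genes, 10 of them higher and 64 lower. Among the higher genes of the authors' deposited table were Wdr77 (q = 2.60e-38), Npy (q = 0.0296) and Ifit1 (q = 0.0472), and among the lower ones Myh1 (q = 1.06e-78) and Acta1 (q = 2.03e-76). Of its 49 genes marked as higher, 36 had their highest value in BCP replicate 2.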

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

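The alternatives were chosen before the data were examined, except for the mitochondrial feature covariate and the fit without muscle genes. The reported counts were 2 genes higher, 23 lower, 2 lists higher and 10 lower. Pseudocounts of 0.1 and 0.01, median-ratio rescaling, quantile normalization, limma without the trend and an adjusted p under 0.1 left the counts they bear on within 1.5 times. The count higher was 1 with no filter, 1 with a mean FPKM of at least 5 and 1 without muscle genes, where the count lower was 7 because the genes removed include most of the calls. That fit removed only genes of the skeletal muscle list or with a muscle term, so it may still hold muscle genes. Array weights, whose estimation stopped before its convergence tolerance was reached, gave 4 higher, 35 lower, 0 lists higher and 5 lists lower, and an unadjusted p under 0.05 with a fold of at least 2 gave 11 higher and 48 lower. An estimated correlation gave 0 lists in each direction, and fry 0 higher and 1 lower. The mitochondrial covariate gave 8 lists higher. Leaving out each replicate gave 0 to 7 genes higher, 13 to 24 lower, 0 to 11 lists higher and 3 to 10 lists lower. The cause was not tested except where named.

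Numbers 1 and 3 occur in both groups. Deviations from the group means correlated at 0.0643 for number 1 and -0.104 for number 3, which gives no sign of pairing but cannot exclude a shared batch. Both samples of number 1 were the highest in the unnamed mitochondrial features (2479 FPKM in BCP and 2208 in sBCP). Those of number 3 differed (1349 in BCP and 471 in sBCP). With the replicate block, over the 4 shared samples or all 6, limma called 10 genes higher and 28 lower and camera 1 list higher and 12 lower. Of these 10 higher genes 0, and of the 28 lower ones 19, were among those reported. The adjusted p of Wdr77 was 0.0919 over the 4 and 0.0884 over all 6, and that of LOC103692785 was 0.128 and 0.121. Des, which was not called in the reported fit, was called lower with the block (limma adjusted p of 0.0419 and 0.0401). Among lists called with or without the block, mean differences that changed direction under it, in both forms, were -0.186 for axon injury, -0.469 for macrophages, -0.287 for cytokines, -0.0945 for interferon, -0.633 for MHC class II and -0.402 for complement. BCP replicate 2 and sBCP replicate 4 have no partner number, so neither form uses them for the group difference, and both give the same means. The block cannot be told apart from the loss of these samples. The array weights, which had not converged, turned neutrophil (0.10) and erythroid genes (0.0281). Leaving out each replicate gave means from -0.118 to 0.522 for axon injury, from -0.321 to 0.437 for macrophages, from -0.445 to 0.489 for MHC class II and from -0.233 to 0.367 for complement, each lowest without BCP replicate 2 and highest without BCP replicate 3.

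Of 3369 refits of the 192 genes named or called, 3166 kept direction and side of the threshold, 83 lost a call, 12 gained it, 0 called genes changed direction and 108 uncalled ones did. Of 734 refits of the 37 lists, 545 kept both, 68 lost a call, 35 gained it, 18 changed direction with a call before or after, and 68 changed direction uncalled. A count test was not run, since whole reads were not recovered. Depth limits what can be said of genes near 1 FPKM.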

Other observations

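All tests of explanations in this part were chosen after the results were seen. Of the tested features, 7 were at 5 FPKM or more and at least 4 times the next library in BCP replicate 2, against 0 or 1 in each other library. Over all 23800 features, 17 were in BCP replicate 2, against 0 to 4 in each other library. Beside Npy and Atf3 the 7 tested ones included Cxcl13, a chemokine that attracts B cells, at 29.4 FPKM with 5.22 in the next library, and Stac2 at 21.4 FPKM with 2.09. A pro-neuropeptide Y-like feature, LOC100912228, was at 263 FPKM with 7.03 in the next library, and can share reads with Npy. These genes were named after their values were seen.

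Unnamed mitochondrial features at positions 68 to 1025 and 1094 to 2664 summed to 2479 FPKM in BCP replicate 1, 1349 in BCP replicate 3 and 2208 in sBCP replicate 1, and to 511, 471 and 319 in BCP replicate 2 and sBCP replicates 3 and 4. A feature described as 7S RNA 2 lies on chromosome 6. It was at 319, 150 and 284 FPKM in the former libraries and at 22.3, 34.9 and 18.3 in the latter. All mitochondrial features together, the unnamed ones included, made up 7.44%, 8.35% and 9.99% of the summed FPKM in the former libraries. They made up 8.89%, 9.01% and 7.54% in the latter, so the unnamed features do not stand for mitochondrial content as a whole.

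Skeletal muscle genes were lower in every BCP library. The scaling factors of the libraries span 0.11 on the log2 scale, far less than the median difference of -4.02, which argues against the authors' scaling. Skeletal muscle tissue taken along with the sBCP ganglia may be a source: of 17 list members at 1 FPKM or more, 13 (76.5%) were higher in all sBCP than in all BCP libraries, with Acta1 at 198 and Mylpf at 136 FPKM in sBCP. This fell short of the 80% set for the test and leaves it undecided. A higher share could not have decided it either, since a change of muscle genes inside ganglion cells could give it as well. Among the exceptions, Pvalb, which the list of large-diameter neurons also holds, was at 308 to 412 FPKM over the libraries. The others, Myh7, Tnnc1 and Tnnt1, did not exceed 5.79 FPKM in any library. The shortfall does not argue against such tissue. A change inside ganglion cells with tumour cannot be told apart from this, since the gap between groups (2.93 in list score) follows the group and the labels record no dissection. The 3 against 3 design has 10 splits, too few for a share under 0.05; the real one called 25 genes and the highest other 9.

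Axon injury genes were high in BCP replicate 2 (list score of 0.98), as were MHC class II (1.14), macrophage (0.91), cytokine (0.75) and complement genes (0.74). A tumour effect of about that size shared by the group is argued against by the higher of the other BCP libraries, -0.0857 from the mean sBCP score (whose libraries span 0.28), where BCP replicate 2 lay at 1.13. Scaling of that library is argued against by its median centred value over all genes, 0.0117, its depth (1.31) by a gap of 1.28 to BCP replicate 3, the nearest in depth (1.23), and low mitochondrial features by a gap of at least 1.14 to the other libraries low in them. A swap with an sBCP sample after dissection is argued against by its muscle score, which lay -3.25 from the lowest sBCP score. If that score reflects muscle taken along at dissection, it cannot test an earlier swap. A smaller shared effect, nerve damage or a stronger tumour effect in that sample, an earlier swap, and a swap with an outside sample stay open and were not tested.

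For the lists, the 10 splits are again too few for a share under 0.05. The real split called 12 lists and the highest other 21, and 8 splits, the real one included, called at least 12. The number of lists called therefore does not set the real grouping apart from the other splits. The split of BCP replicates 1 and 2 with sBCP replicate 4 against the rest had 2500 genes at an unadjusted p under 0.05 against 271 for the real one, and called 0 genes and 8 lists.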
